A study of Mus musculus with 6 samples.

How the data were processed

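Gene expression was measured in 6 samples of V6.5 mouse embryonic stem cells, each hybridised to a GeneChip Mouse Gene 1.0 ST array, a one-colour array that reads each transcript with a set of probes (a probe set). The cells carried a doxycycline-inducible short hairpin RNA and were grown with doxycycline (dox) at 1 µg/ml or without it. Per the labels, hairpin 1 and hairpin 2 targeted Pcgf6 and a scrambled hairpin served as control. Per the labels' protocols, the stem cells were cultured on inactivated mouse embryo fibroblasts as feeder cells, and RNA from feeder cells can therefore be part of a sample.

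The deposited values are on a log2 scale and were made by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a set, so a change shared by most genes is removed. Tool versions and options were not given in the sources used here. The values ran from 2.28 to 14.27, and the medians of the arrays lay between 7.02 and 7.08. No value column was left unmatched to a sample. Correlations between arrays across genes ranged from 0.990 to 0.997, and at most 0.0984% of probe sets held an identical value on a pair of arrays, so no array entered more than once.

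Of 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 had none. By Entrez identifier, 21698 of the probe sets with 1 symbol were found in the RefSeq annotation of GRCm38.p6, which was used for names, chromosome membership and neighbouring genes only. Genes were named only from probe sets with 1 symbol, apart from the Zscan4 copies, named after their values were seen. For the 999 genes with several such probe sets, the one with the highest mean over the 6 arrays was used, which left 19938 genes, all tested without a filter on level.

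The analysis started from the deposited log2 values and used limma 3.58.1 in R 4.3.3. The samples formed 4 groups: induced Pcgf6 hairpins (n = 2), uninduced Pcgf6 hairpins (n = 2), induced scrambled (n = 1) and uninduced scrambled (n = 1). A model with 1 mean per group was fitted over all 6 arrays, with 2 residual and 4.44 prior degrees of freedom. Its contrasts were induced against uninduced Pcgf6 hairpins, the difference between that change and the change of the scrambled pair, and uninduced Pcgf6 hairpins against uninduced scrambled. A model of 2 groups compared the induced Pcgf6 hairpins with the 4 other arrays pooled, with 4 residual and 4.01 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. The scrambled arrays were single, so their spread was taken to equal that of the hairpin groups. The number of arrays limits the precision. The arrays of a hairpin group carried different hairpins, and the labels do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical. Errors printed as SE are moderated standard errors from limma.

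Changes within a pair are the induced minus the uninduced array of the same hairpin, each from 1 array against 1, and counts past 1.5-fold carry no test. Gene lists, 17 in all, were fixed before the data were examined from general knowledge of the field; the germ-cell list included genes known to be repressed by Pcgf6-containing complexes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists. The median of each list was placed among 10000 random lists of the same size matched on mean expression. With an estimated correlation camera used the 2 residual degrees of freedom, so a lost call need not reflect correlation between members. Members without a probe set of their own, among them T, Cdkn1a and Zscan4c, were left out of the gene and list tests, and probe sets shared by several symbols were tested only where all probe sets were.

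The genes named were set by a rule written before the data were examined: Pcgf6; the 12 highest and 12 lowest genes by the smaller of both per-hairpin changes, at least 1.5-fold the same way; the 5 highest and 5 lowest of each other comparison, among called genes where at least 10 were called; up to 4 members of each list with the strongest mean change, and all members of a list that passed the test. All members of the pluripotency, mesoderm and PRC1.6 lists could be named. Predicted, RNA-only and olfactory or vomeronasal receptor models were skipped by the pattern of their symbols, which did not cover the non-coding transcript Platr8. Any other gene is named with a statement that it was chosen after its values were seen.

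The hairpin number pairs the induced and uninduced arrays, because both come from cells carrying the same hairpin. Deviations of same-numbered arrays from their group means correlated at 0.181 across genes, and a fit with the hairpin as a block was run as an alternative. The other alternatives were median centring, quantile normalization, and leaving out the dimmest 25% or 50% of genes. Others tested all probe sets or averaged the probe sets of a gene. Further ones were an intensity trend or a robust estimate in the variance prior, the 4 hairpin arrays alone and a 2-fold threshold. Camera with an estimated correlation, the rotation test fry, and leaving out each hairpin array in turn completed the set. A feeder score as a covariate, leaving out a scrambled array, and correlations in the brighter genes without the feeder list were chosen after seeing the data. The feeder score lowers the residual degrees of freedom, as leaving out an array does, so fewer genes can pass.

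The fits were tested on simulated data drawn from the real gene means and the fitted spread, with 200 of 19938 genes changed in each of 5 runs. For induced against uninduced hairpins, 27.5% of genes changed 1.5-fold, 88.4% changed 2-fold and 99.7% changed 4-fold were recovered, and 3.9% of calls were false. For the difference from scrambled, recovery was 0.3%, 10.1% and 91.2% at the same sizes, with 4.3% false calls. For the pooled comparison it was 73.4%, 97.0% and 100%, with 4.5% false calls. The simulated arrays held independent noise and no line, pair or feeder differences, so these rates may not hold for the real arrays.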

Results

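Transcript levels were measured on 6 arrays of V6.5 mouse embryonic stem cells in which a hairpin against Pcgf6 could be switched on with doxycycline. Pcgf6 encodes a polycomb group RING finger protein of the variant repressive complex PRC1.6. Each of 2 Pcgf6 hairpins and a scrambled hairpin was measured on 1 array with dox and 1 array without. Each such couple of arrays is called a pair. Values are log2 expression, and the number of arrays limits their precision. The series title names mesodermal differentiation and reprogramming as the study's subject.

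The knockdown was examined first. Pcgf6 (probe set 10468275) averaged 9.33 ± 0.09 (SD, n = 2) on the log2 scale with dox and 11.63 ± 0.10 (SD, n = 2) without dox in the Pcgf6-hairpin cells. The change was -2.17 under hairpin 1 and -2.44 under hairpin 2. Across both hairpins the change of Pcgf6 was -2.30 (SE 0.10) on the log2 scale, a 4.94-fold fall, with an adjusted p of 0.000846 by limma. In the scrambled pair it measured 11.82 with dox and 11.80 without, a difference of 0.02.

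**Figure D1:**
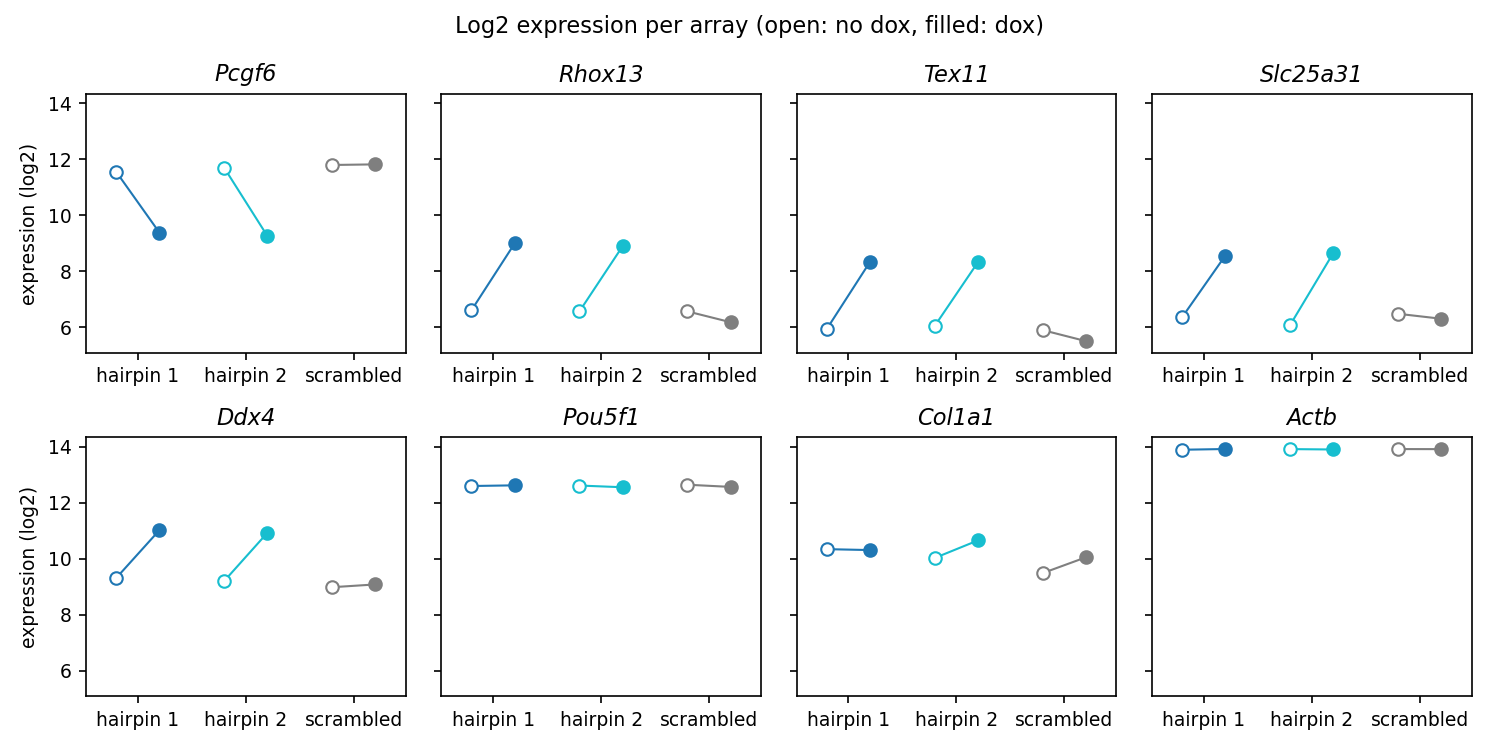
Log2 expression (y axis) of 8 genes on each of the 6 arrays, by hairpin (x axis), with open points for no dox, filled points for dox and a line joining the arrays of a pair. Pcgf6 is lower with dox under both Pcgf6 hairpins (9.39 and 9.27 against 11.56 and 11.70) and Rhox13, Tex11, Slc25a31 and Ddx4 are higher there, while their scrambled pairs differ by between -0.39 and 0.10.

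The main comparison asked which genes changed with dox in cells carrying a Pcgf6 hairpin. Among genes with a probe set of their own, Rhox13, an X-linked reproductive homeobox gene, rose by 2.36 (SE 0.09, n = 2 against 2, limma adjusted p = 0.000789) on the log2 scale, or 5.13-fold, from 6.59 ± 0.03 to 8.95 ± 0.07 (SD, n = 2). Tex11, which acts in meiotic recombination, rose by 2.34 (SE 0.09, adjusted p = 0.000789), and Slc25a31, the ADP/ATP carrier of male germ cells, by 2.39 (SE 0.12, adjusted p = 0.00134). Mael, which acts in piRNA silencing of transposons, rose by 1.98 (SE 0.08), and the piRNA helicase gene Mov10l1 by 1.95 (SE 0.09). In the scrambled pair the same 5 genes differed by -0.39, -0.39, -0.18, -0.65 and 0.11.

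By limma, 40 of 19938 genes passed the threshold, of which 38 rose and 2 fell. The rises ranged from 0.73 to 2.39 on the log2 scale, and all 38 genes were higher with dox under each hairpin. The scrambled pair differed by less than 1.5-fold for 36 of the 38 and was below 0 for 30. Their median level without dox was 6.56, against 7.56 over all genes. The other genes named among the highest 12 were Tex13b, Syce1, Tdpoz3, Ddx4, Calb2, Tdrkh and Taf7l, with rises between 1.57 and 2.06. Syce1 encodes a protein of the synaptonemal complex, Ddx4 the germ-cell RNA helicase Vasa and Taf7l a germ-cell subunit of the transcription factor TFIID. Calb2 encodes the calcium-binding protein calretinin and rose by 1.72 (SE 0.19, adjusted p = 0.0418). The gene Calb2 did not pass with quantile normalization (adjusted p = 0.0518), nor with 3 of the 4 hairpin arrays left out in turn, nor in the difference from scrambled (adjusted p = 0.615).

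Besides Pcgf6, the gene that fell was Calcr, the calcitonin receptor gene, by 0.83 on the log2 scale (SE 0.10, adjusted p = 0.047). The gene Calcr did not pass with any of the 4 hairpin arrays left out (adjusted p between 0.101 and 0.387), nor in the difference from scrambled (adjusted p = 0.678). The other genes named among the 12 lowest did not pass. These included Sall2 (-0.81, SE 0.10, adjusted p = 0.066), the transcription factor gene Zic2 (-0.77, SE 0.10, adjusted p = 0.0684) and the de novo DNA methyltransferase gene Dnmt3b (-0.65, SE 0.08, adjusted p = 0.0688). Foxi3, Slc6a15, Zfp459, Fabp3, Pipox, Platr8 and Gab1 measured between -0.88 and -0.65, with adjusted p between 0.0707 and 0.538. In the scrambled pair Sall2, Fabp3 and Pipox also measured -0.53, -0.50 and -0.55, each with an adjusted p of 0.999 for the difference. With the hairpin as a block the gene Sall2 (adjusted p = 0.0331) and Zic2 (adjusted p = 0.0491) passed, and with median centring Sall2, Zic2 and Dnmt3b (adjusted p = 0.0498) did. An unadjusted p under 0.05 was reached by 1745 genes, where chance gives 997. The count was 24 without induced hairpin 1, 26 without induced hairpin 2 and 14 without the uninduced array of either hairpin. It was 7 without the dimmest 50% of genes, 62 with an intensity trend and 21 with a feeder score as a covariate, chosen after seeing the data.

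The germ cell and meiosis list held 31 measured members, of which 12 rose, 0 fell and 19 did not pass. Adjusted over the list alone, 21 rose and 0 fell. The list was fixed in advance but drew on genes known as targets of Pcgf6-containing complexes. Beyond the genes above, Piwil2, a germ-line Argonaute gene, rose by 1.46 (SE 0.08), the RNA-binding protein gene Dazl by 0.94 (SE 0.09), Sycp2 of the synaptonemal complex by 0.85 (SE 0.09) and Rnf17 by 0.73 (SE 0.09, adjusted p = 0.0487). Dazl, Sycp2 and Rnf17 did not pass with any of the 4 hairpin arrays left out, and the gene Rnf17 not with quantile normalization either (adjusted p = 0.0574). The median change was 0.69 under hairpin 1 and 0.71 under hairpin 2, both above all 10000 random lists, and -0.14 in the scrambled pair, below all of them. Camera gave an adjusted p of 2.88e-40 at its preset correlation and an adjusted p of 0.0759 with an estimated correlation. The estimated correlation was 0.00226, below the preset 0.01, so correlation between members did not account for the weaker value. With the rotation test fry the adjusted p was 0.00955. The feeder fibroblast list had medians of -0.01, 0.44 and 0.56 in the hairpin 1, hairpin 2 and scrambled pairs.

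Of the 2-cell-like state list, which marks a rare state resembling the early embryo, 8 of 14 members were measured. Tdpoz3 (1.73, SE 0.09), Usp17la (1.07, SE 0.09) and Zfp352 (0.87, SE 0.10) rose, 0 fell and 5 did not pass. Levels of these genes were low, averaging 4.46, 4.86 and 5.70 without dox and 6.19, 5.93 and 6.57 with dox in the Pcgf6-hairpin cells. The lower quartiles of the arrays lay between 5.5 and 5.56. Zfp352 did not pass with any of the 4 hairpin arrays left out. Adjusted over the list alone, 5 rose and 0 fell. Members read only by probe sets shared between symbols had no part in this list. Probe sets shared by Zscan4 copies, chosen after their values were seen, rose by 2.38, 2.39 and 2.44 over both hairpins. Their limma adjusted p lay between 0.0329 and 0.0391 over all probe sets. In the scrambled pair they measured -0.68, -0.68 and -0.76. Tdpoz3 and Usp17la belong to families of near-identical copies, so their values are uncertain. Medians were 0.85, 0.48 and -0.13 in the hairpin 1, hairpin 2 and scrambled pairs, and camera gave an adjusted p of 3.63e-09, with an adjusted p of 0.425 with an estimated correlation.

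None of the 24 pluripotency genes passed over all genes tested. Adjusted over the list alone, Tcl1 (0.63, SE 0.09) and Tbx3 (0.45, SE 0.11) rose and Dppa4 (-0.45, SE 0.08) fell, and 21 did not pass. A second probe set of Dppa4 measured -0.28 over both hairpins. The scrambled pair measured -0.43 for Tcl1, 0.17 for Tbx3 and -0.33 for Dppa4. The core factors Pou5f1 (-0.02, SE 0.08), Sox2 (-0.10, SE 0.08) and Nanog (0.01, SE 0.10) did not pass by either adjustment. The median was 0.00 under hairpin 1, -0.11 under hairpin 2 and -0.09 in the scrambled pair, and the adjusted p of camera was 0.432.

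Of the primitive streak and mesoderm list, 26 of 28 members were measured and 0 rose or fell, also when adjusted over the list alone. The members left out were T, which had no probe set of its own, and Foxf1a, another name of the measured gene Foxf1. Pdgfra measured 0.41 (SE 0.40), the signalling gene Wnt3 0.37 (SE 0.15), Tbx20 0.30 (SE 0.09) and Gsc -0.24 (SE 0.10). Medians were 0.04, 0.03 and 0.07 in the hairpin 1, hairpin 2 and scrambled pairs, and the adjusted p of camera was 0.364. The streak genes Mixl1 and Eomes measured 0.19 (SE 0.11) and 0.12 (SE 0.19) with the hairpins. They measured 1.40 and 0.72 in the scrambled pair, which has no replicate and in which the feeder list had a median of 0.56. Under hairpin 2, where the feeder median was 0.44, Mixl1 and Eomes measured 0.27 and 0.24. Whether feeder cells contributed to these values was not tested.

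In the ectoderm list, 0 of 16 measured members passed over all genes, and Zic2, Zic5 (-0.61, SE 0.10), Fgf5 (-0.50, SE 0.09), Otx2 (-0.50, SE 0.15) and Pax6 fell when adjusted over the list alone, Pax6 being named after its values were seen. A second probe set of Zic5 measured -0.39 over both hairpins. Camera gave an adjusted p of 0.000852 for a lower list, and an adjusted p of 0.467 with an estimated correlation. Medians of the ectoderm list were -0.09, -0.18 and 0.00 in the hairpin 1, hairpin 2 and scrambled pairs. Zic2, Zic5, Fgf5 and Otx2 measured 0.12, -0.36, 0.58 and 0.00 in the scrambled pair. In the trophectoderm list, 0 of 13 passed, and the keratin genes Krt8 (0.58, SE 0.10) and Krt18 (0.56, SE 0.12) rose when adjusted over the list alone. Camera gave an adjusted p of 0.00388 for a higher list, and an adjusted p of 0.425 with an estimated correlation. The scrambled pair measured 0.58 for Krt8 and 0.29 for Krt18. Medians of the trophectoderm list were 0.10, 0.09 and 0.18 in the hairpin 1, hairpin 2 and scrambled pairs.

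Other members of PRC1.6 did not pass, so that of 16 genes Pcgf6 alone fell, both over all genes and adjusted over the list alone. E2f6 measured 0.33 (SE 0.09), Hdac2 0.29 (SE 0.09) and Mga -0.29 (SE 0.10). In the blood and endothelium list, 0 of 20 passed. Adjusted over that list alone, Kit (0.60, SE 0.09) rose, and Etv2 (-0.54, SE 0.10) and Cdh5 (-0.36, SE 0.09) fell. The scrambled pair measured 0.03 for Kit, -0.55 for Etv2 and -0.30 for Cdh5. The lists of other polycomb genes (21 measured), endoderm (18), Hox genes (23), proliferation (20), p53 targets (11), interferon response (16), amino acid stress (13) and housekeeping (8) had 0 members past the threshold by either adjustment. Their camera adjusted p ranged from 0.0656 for proliferation to 0.914 for p53 targets.

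The feeder fibroblast list, markers of the cells on which the stem cells were grown, had 20 measured members, none past the threshold by either adjustment. Lox (0.38, SE 0.22), Col5a2 (0.37, SE 0.14), Mmp2 (0.31, SE 0.17) and the collagen gene Col1a1 (0.30, SE 0.15) had the strongest mean changes. The mean level of the list was 10.10 with and 10.08 without dox for hairpin 1, 10.41 and 9.96 for hairpin 2, and 9.77 and 9.24 for scrambled. Camera gave an adjusted p of 1.37e-05 for a higher list, and an adjusted p of 0.631 with an estimated correlation. No list call of camera held with an estimated correlation.

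**Figure D2:**
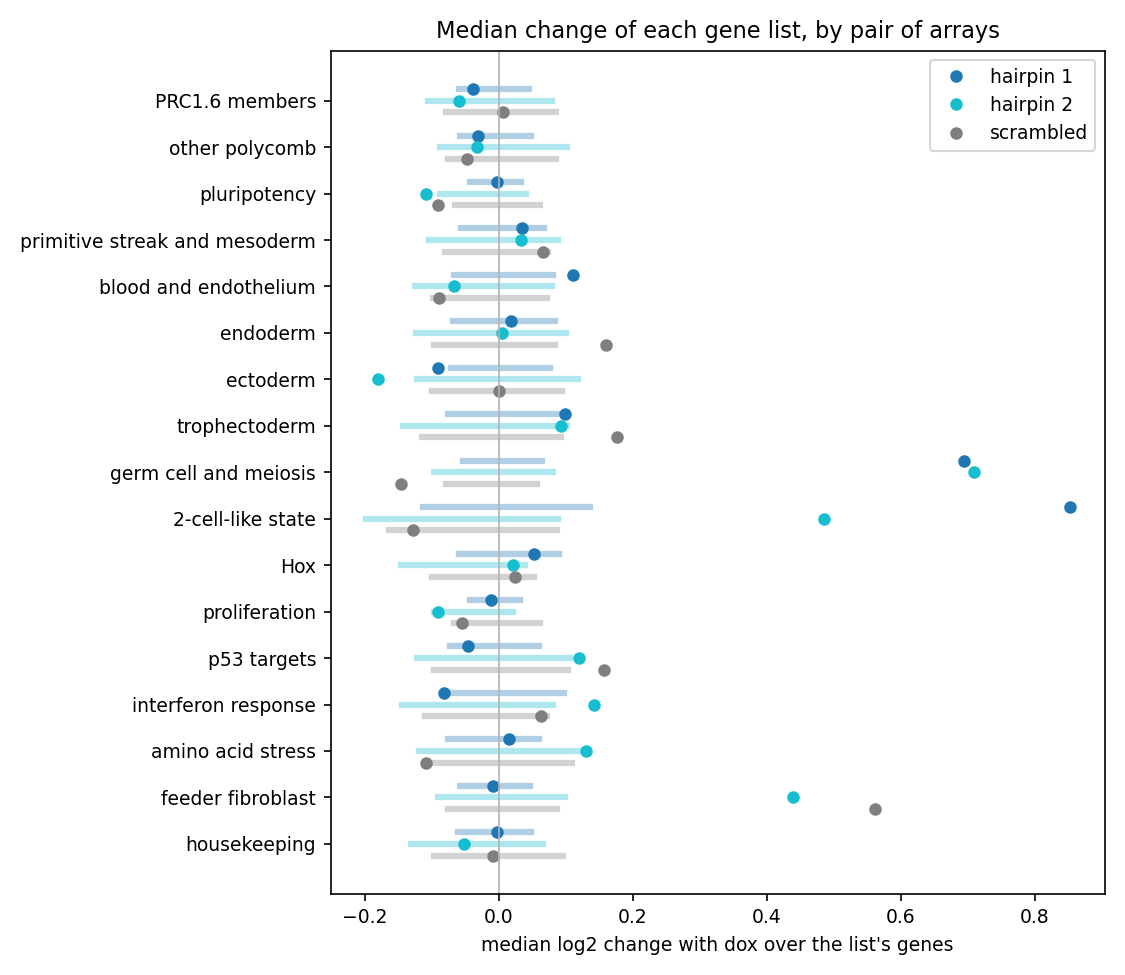
Median log2 change with dox (x axis) of each of 17 gene lists (y axis), with 1 point per pair of arrays and bars for the range of 10000 random lists of the same size and level with 2.5% left out at each end. The germ cell and meiosis list lies at 0.69 and 0.71 under the Pcgf6 hairpins and at -0.14 in the scrambled pair, and the feeder list at -0.01, 0.44 and 0.56.

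A second comparison asked whether the response to dox differed between the Pcgf6 hairpins and the scrambled hairpin. The difference was largest for the germ-line genes Rhox13 (2.75, SE 0.15, limma adjusted p = 0.00645), Tex11 (2.73, SE 0.15, adjusted p = 0.00645) and Mael (2.64, SE 0.14, adjusted p = 0.00645), with positive values for a higher response with the Pcgf6 hairpins. Slc25a31 differed by 2.57 (SE 0.20) and Syce1 by 2.31 (SE 0.21). Pcgf6 differed by -2.33 (SE 0.17, adjusted p = 0.0256). Of 19938 genes 14 passed, 13 of them higher, including 8 of the germ cell and meiosis list and 2 of the 2-cell-like state list. An unadjusted p under 0.05 was reached by 908 genes, where chance gives 997. With the hairpin as a block 23 genes passed, and with median centring 22. The count was 9 without the dimmest 25% of genes, 4 without the dimmest 50%, 0 over all probe sets, 0 with a feeder score as a covariate (chosen after seeing the data), 4 without induced hairpin 1, 3 without induced hairpin 2 and 0 without the uninduced array of either hairpin.

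A further comparison set the induced Pcgf6 hairpins against the 4 other arrays pooled. Tex11 was higher by 2.49 (SE 0.14, limma adjusted p = 0.000189), Rhox13 by 2.47 (SE 0.13), and Slc25a31, Mael (2.17, SE 0.19) and the testis-expressed gene Tex13b (2.07, SE 0.12) followed. Pcgf6 was lower, at -2.39 (SE 0.09, adjusted p = 4.98e-05), followed by the zinc finger gene Zfp459 (-0.88, SE 0.12), the aquaporin gene Aqp3 (-0.74, SE 0.11), Zfp229 (-0.73, SE 0.11) and Hsf2bp (-0.67, SE 0.10). In all 82 genes passed, 70 higher and 12 lower, and 17 of the higher genes belonged to the germ cell and meiosis list. An unadjusted p under 0.05 was reached by 2382 genes. With the hairpin as a block 39 passed, 36 higher and 3 lower, and Zfp459 (adjusted p = 0.164), Aqp3 (adjusted p = 0.179), Zfp229 (adjusted p = 0.171) and Hsf2bp (adjusted p = 0.264) no longer did. The count was 38 without the dimmest 50% of genes and 42 with a feeder score as a covariate, chosen after seeing the data. It was 24 without induced hairpin 1, 28 without induced hairpin 2, 45 without uninduced hairpin 2 and 54 without the induced scrambled array.

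Uninduced Pcgf6-hairpin cells were compared with uninduced scrambled cells, which addresses differences between the lines before induction. The highest values belonged to the matrix metalloproteinase genes Mmp3 (1.93, SE 0.68, n = 2 against 1) and Mmp13 (1.71), the mast cell protease gene Mcpt8 (1.93) and the chemokine genes Ccl2 (1.75) and Ccl11 (1.74), and the lowest to H2ac4 (-0.98, SE 0.15), Calcoco2 (-0.92), Ltb (-0.81), Pck2 (-0.75) and Sfn (-0.74). None passed: limma called 0 of 19938 genes, the smallest adjusted p was 0.183, and 1607 genes had an unadjusted p under 0.05 where chance gives 997. Pcgf6 measured -0.17 (SE 0.12, adjusted p = 0.802). The mean level of the feeder list was 10.08 and 9.96 in the uninduced hairpin arrays and 9.24 in the uninduced scrambled array. Camera called the list higher (adjusted p = 3.81e-19, and adjusted p = 0.672 with an estimated correlation) and the pluripotency list lower (adjusted p = 5.9e-06, and adjusted p = 0.729 with an estimated correlation). It also called the trophectoderm list lower (adjusted p = 0.0358) and the amino acid stress list lower (adjusted p = 0.033), each with an adjusted p of 0.672 with an estimated correlation. Of these lists, trophectoderm alone kept its call with the rotation test fry.

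The scrambled pair describes what accompanied dox without a Pcgf6 hairpin, with no replicate and no test. At 1.5-fold, 296 genes were higher and 42 lower with dox. The highest were Mixl1 (1.40), the epidermal gene Lce1h (1.36), the protocadherin gene Pcdh7 (1.20), the mesenchymal homeobox gene Prrx1 (1.11), itself on the feeder list, and the nuclear receptor gene Nr4a2 (1.08). The lowest were the synaptonemal complex gene Sycp3 (-1.16), the histone genes H2bc1 (-1.06) and H2ac4 (-1.02), Lce3b (-0.89) and the meiosis gene Meioc (-0.85). All 20 feeder genes were higher in this pair, with a median of 0.56.

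The 3 responses were then set side by side gene by gene. At 1.5-fold, 125 genes were higher and 48 lower under hairpin 1, and 432 higher and 89 lower under hairpin 2. Both hairpins shared 67 higher and 14 lower genes and had 0 in opposite directions, where independent lists would share 2.71 higher and 0.21 lower genes. At 2-fold, they shared 27 higher genes and 1 lower. Hairpin 2 and scrambled shared 107 higher and 2 lower genes with 8 opposite, where independent lists would share 6.41, 0.19 and 2.23. Hairpin 1 and scrambled shared 3 higher and 2 lower genes with 5 opposite, where independent lists would share 1.86, 0.10 and 0.98.

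Across genes, which are not independent replicates, the changes under both hairpins correlated with a Pearson r of 0.357 and a Spearman rho of 0.227. Hairpin 2 and scrambled gave 0.341 and 0.274, and hairpin 1 and scrambled 0.00993 and 0.0250. In the hairpin 2 and scrambled pairs all 20 feeder genes were higher with dox, against 9 of 20 in the hairpin 1 pair. No array entered more than 1 of the 3 responses.

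**Figure D3:**
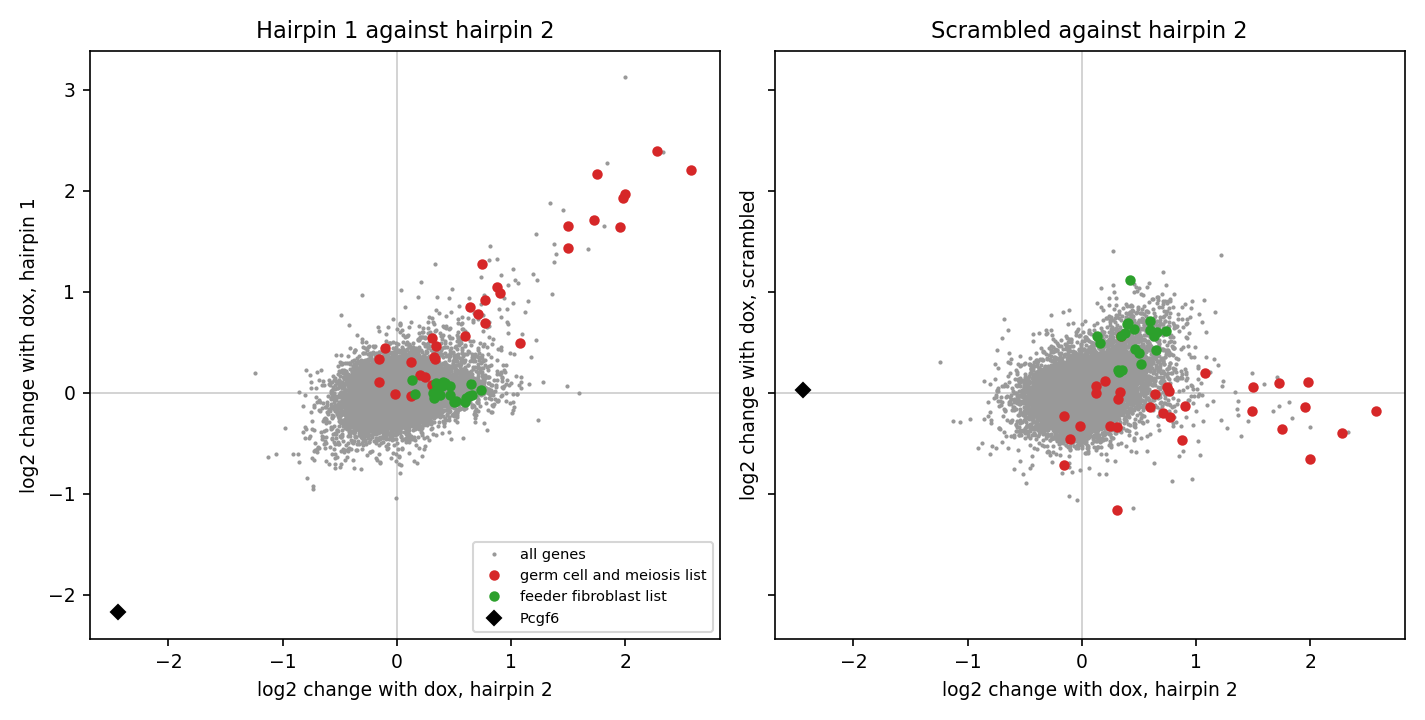
Log2 change with dox of each gene (grey points) under hairpin 2 (x axes) against hairpin 1 (left) and scrambled (right), with the germ cell and meiosis list in red, the feeder list in green and Pcgf6 as a diamond. Germ-line genes lie along the diagonal on the left and near or below 0 for scrambled on the right, where the feeder genes are higher on both axes, with medians of 0.44 and 0.56.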

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

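The tests that bear on the germ-cell and feeder patterns were chosen only after the results were seen. The tests of explanations for the X-linked pattern and the comparison of responses between hairpins were fixed before their values were seen. The X-linked share itself was not among the planned tests, so its Fisher p describes a pattern found in the same genes.

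Germ-cell genes rose with dox under both Pcgf6 hairpins, where 12 of 31 members passed and camera gave an adjusted p of 0.0759 with an estimated correlation, and the response of 8 members differed from the scrambled pair by limma, a comparison with 0 calls over all probe sets, with the feeder score or without either uninduced hairpin array. A response to dox itself is argued against, for 1 pair of arrays, by the scrambled pair's median of -0.145, below all 10000 random lists. Random lists do not measure the spread between arrays. In that pair the pluripotency and trophectoderm lists also lay at extremes, at percentiles 0.26 and 99.98. An off-target effect of 1 hairpin is argued against by the smaller of both hairpin medians, 0.694, above all random lists, and a larger share of feeder cells by the feeder median of -0.009 in the hairpin 1 pair. Loss of Pcgf6 is a candidate explanation, as a hypothesis found and tested on the same data. Off-target effects shared by both hairpins stay open, untested.

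Feeder-fibroblast genes were higher with dox in the hairpin 2 and scrambled pairs, with medians of 0.44 and 0.56, and Col1a1 rose from 10.03 to 10.65 and from 9.48 to 10.05 there, while the abundant gene Fn1, named after its values were seen, went from 12.91 to 13.27 and from 13.01 to 13.23, with no test of a single pair. A response to dox itself is left open. The median was -0.009 in the hairpin 1 pair, 0.45 below the hairpin 2 median, but each pair holds 1 array against 1. The error of a change within a pair is therefore not known. The mean of the list varied with an SD of 0.46 (n = 3) between arrays without dox. These arrays carry different hairpins, so that SD is not the error of a change within a pair. A different share of feeder cells between arrays and differentiation of stem cells towards fibroblasts cannot be told apart: the share of members with the direction of the list was 100% in the hairpin 2 pair, which restates the pattern, and in uninduced hairpin 1 against uninduced scrambled (median 0.87), and both explanations would give it. No other fixed list holds a member of the feeder list, and how many members the stem cells themselves express was not tested.

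Among the 38 genes that rose, 10 were X-linked (26.3%), against 3.72% of 19856 tested genes with a chromosome (odds ratio 9.35, two-sided exact Fisher p = 8.81e-07). A shift of the whole X chromosome is argued against by the genes that were not called, where the X-linked median lay -0.0093 from the autosomal one on the log2 scale (bootstrap SE 0.00649). Counting neighbours within 10 genes once left 9 of 37 X-linked, with a two-sided exact Fisher p of 6.3e-06, so a single cluster counted several times is argued against. Whether germ-line genes as a class are more often X-linked was not tested, and no biological explanation was tested.

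The other results differed between the Pcgf6 hairpins and the scrambled pair by limma's test of the difference, given on the log2 scale with positive values for a higher response with the Pcgf6 hairpins. The values were 2.75 for Rhox13, 2.73 for Tex11, 2.64 for Mael, 2.57 for Slc25a31, 2.31 for Syce1 and 1.93 for Tdrkh. They were 1.87 for Tdpoz3, 1.84 for Mov10l1, 1.69 for Usp17la, 1.64 for Piwil2, 1.62 for Ddx4 and -2.33 for Pcgf6. Gm4779 and Hormad2, named after their values were seen, differed by 1.82 and 1.55.

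By camera at its preset correlation, the same difference was called for 5 lists, none of which kept the call with an estimated correlation. With the rotation test fry the germ cell and meiosis list kept its call and the other lists did not. The median difference was 0.76 for germ cell and meiosis (adjusted p = 0.0717 with an estimated correlation), 0.97 for the 2-cell-like state (adjusted p = 0.471) and 0.16 for amino acid stress (adjusted p = 0.471). It was -0.05 for primitive streak and mesoderm (adjusted p = 0.557) and -0.31 for feeder fibroblast (adjusted p = 0.638).

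Among 13767 probe sets with no gene symbol or several, which entered only the tests of all probe sets, 17 passed the threshold for induced against uninduced Pcgf6 hairpins, 15 of them higher. They are part of 40 calls over all probe sets, of which 23 had 1 symbol. Of the 17, 4 had no symbol and 13 had several. The 13 cover 4 sets of symbols, among them the Zscan4 copies given with the 2-cell-like state list, so they are not separate transcripts. In the scrambled pair 4 changed by at least 1.5-fold, all 4 in the opposite direction, from 2 sets of symbols or unnamed probe sets.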

How the results depend on the processing

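The feeder score, the scrambled arrays left out in turn and the correlations in the brighter 50% of genes without the feeder list were chosen only after the results were seen; the other alternatives were set beforehand. The change of Pcgf6 kept its direction and passed under every alternative run for it, from -2.38 to -2.23 on the log2 scale. The uninduced comparison gave 0 calls in limma under each of its alternatives. Of the 162 other named genes, 19 of them called, none changed direction where it passed in the main or the alternative fit. Changes of direction were not counted where neither fit passed, as for Ltb, at 0.014 and, with median centring, -0.006. Among the named genes 32 values no longer passed, 30 of them with an array left out, and 16 newly passed. The number of arrays limits the fits, which rest on fewer residual degrees of freedom with 1 array left out or with the feeder score. A lower count with the feeder score therefore need not mean that feeder cells account for the calls. Where no cause follows from fewer genes or arrays, the cause was not tested.

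For induced against uninduced Pcgf6 hairpins (40 genes), the count was 7 without the dimmest 50% of genes, where 15 of the 40 were still tested, 62 with an intensity trend, all 40 included, and 21 with the feeder score, 20 of them among the 40. It ranged from 14 to 26 with 1 array left out. For the difference from scrambled (14), it was 22 with median centring, 9 and 4 without the dimmest 25% and 50%, 0 over all probe sets, 0 with the feeder score, and 0 to 4 with 1 array left out. For the pooled comparison (82), it was 38 without the dimmest 50%, 42 with the feeder score and 24 to 81 with 1 array left out.

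With the hairpin as a replicate block the difference gave 23 genes, the pooled comparison 39 and the main comparison 54, and Sall2, Zic2 and Meioc passed in the main comparison, where no named gene or list lost its call. All 12 named genes called in the difference kept their call. In the pooled comparison 17 of 23 did, and Zfp459, Gab1, Aqp3, Zfp229, Hsf2bp and Sycp2 did not; the cause was not tested.

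The scrambled pair's 338 genes past 1.5-fold became 1426 over all probe sets and 18 at 2-fold, and the 81 shared by both hairpins became 38 without the dimmest 50%, 298 over all probe sets and 28 at 2-fold. The correlation of both hairpins (0.357) was 0.421 and 0.474 without the dimmest 25% and 50%, that of hairpin 2 and scrambled (0.341) 0.407 and 0.473, and that of hairpin 1 and scrambled (0.00993) 0.0637 without the dimmest 50%. In the brighter 50% without the feeder list these were 0.475, 0.470 and 0.0631. The list holds only 20 measured genes, so leaving it out could barely move a correlation and cannot show what feeder RNA contributes.

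Of 5 lists called by camera, 0 were called with an estimated correlation and 1 with the rotation test fry, the germ-cell list. Without the dimmest 50% of genes 6 were called: 4 of the 5, the 2-cell-like list not being tested there, and endoderm (median 0.190, adjusted p = 0.00649) and proliferation (adjusted p = 0.0239), not called over all genes. The germ-cell median of 0.743 over both hairpins had an adjusted p of 0.0759 with an estimated correlation. With 1 hairpin left out, the list medians ranged from -0.108 to -0.003 for pluripotency, from -0.081 to 0.142 for interferon response, from -0.009 to 0.439 for feeder fibroblast, from -0.067 to 0.111 for blood and endothelium, from -0.045 to 0.120 for p53 targets and from 0.015 to 0.131 for amino acid stress. No group of the tested contrasts held 3 arrays on both sides, so other splits of the samples were not counted.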

Other observations

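The list of primed epiblast genes was chosen only after part of it had been seen, and its test on the remaining members was written before their values were seen; the genes of the next paragraph were also named after their values were seen.

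Of the 38 genes that rose in the main comparison, 15 belonged to a fixed list. The others included Ctsc (0.96), Gstm5 (0.83) and Gbp3 (0.81), and 5 genes picked for known germ-line roles, with no test of the group. Sohlh2, a transcription factor gene of early germ-cell differentiation, rose by 1.39 (SE 0.11, limma adjusted p = 0.00882), and Dmrt1, a transcription factor gene of testis development, by 0.86 (SE 0.10, adjusted p = 0.0418). The RNA-binding protein genes Rbm46 and Boll rose by 1.55 (SE 0.10, adjusted p = 0.00339) and 1.42 (SE 0.12, adjusted p = 0.0102), and the meiotic chromosome gene Hormad2 by 1.33 (SE 0.08, adjusted p = 0.00301). In the scrambled pair these 5 genes differed by -0.27, -0.57, -0.18, -0.08 and -0.22.

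Among the amino acid stress genes, whose list medians were 0.015 and 0.131 in the hairpin 1 and hairpin 2 pairs with 8 of 13 members higher in each, the 4 with the strongest mean change follow. Ddit3, which encodes the stress transcription factor CHOP, measured 1.59 in the hairpin 2 pair, -0.01 in the hairpin 1 pair and 0.08 in the scrambled pair. Slc7a11, the cystine transporter gene, measured 0.93, 0.28 and -0.07, and Atf3 0.80, 0.02 and 0.25 in the same order. Asns measured alike in both hairpin pairs, at 0.27 and 0.23, and -0.04 in the scrambled pair. The hairpins were not tested against each other, since each pair holds 1 array against 1.

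Several genes of primed epiblast, the state after implantation, were lower with dox under both hairpins, among them Zic2, Dnmt3b, Fgf5 and Otx2. In the scrambled pair Zic2, Dnmt3b, Fgf5 and Otx2 measured 0.12, -0.11, 0.58 and 0.00. None of these passed over all genes in the main fit. Zic2 passed with the hairpin as a block, and Zic2 and Dnmt3b with median centring. The hypothesis that Pcgf6 knockdown may lower primed epiblast expression was tested on 9 members not looked at before. Their median was -0.08 under hairpin 1, at percentile 7.36 of random lists, and -0.20 under hairpin 2, at percentile 0.18. For the scrambled pair it was -0.01, at percentile 38.18. The prediction, a median below percentile 2.5 under both hairpins, was not met. The 7 members seen before had medians of -0.58 and -0.62, but the hypothesis came from them. Their median in the scrambled pair was -0.11, with 4 of the 7 lower there, including Sall2 (-0.53) and Zic5 (-0.36).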
